A study of Mus musculus with 6 samples.

How the data were processed

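Total RNA from mouse epididymal white fat was measured on 6 Affymetrix arrays, 3 labelled as control (floxed Fto) and 3 as AFO (floxed Fto with adiponectin Cre), each from an independent RNA pool. Biotin-labelled cRNA was made with a kit for 3' in vitro transcription, per the labels' protocols. The deposited values are on a log2 scale, and per the submitters' processing notes they were made with RMA, which corrects background, normalises by quantiles and summarises the probes of a probe set, in Affymetrix Expression Console 1.4. Quantile normalisation gives the arrays nearly the same distribution (medians 5.35 to 5.43), so a change shared by most genes is not visible in these values, and RMA draws low signals together, so differences of dim genes can be understated. How many mice made a pool, and the genome build behind the probe sets, are not given in the sources used here, and no coordinates are printed.

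The table held 45101 probe sets, of which 64 were controls. By the platform annotation 34945 of the others had 1 gene symbol, 932 had several and 9160 were not listed, and the last 2 kinds were left unnamed and untested. Of the gene IDs, 99.4% were found in the mouse RefSeq gene table (assembly GRCm38.p6), and 0 symbols needed an update. Probe sets of 1 gene with a mean over the 6 arrays at or above the 40th percentile (4.88) were kept, which left 23142, and each gene was read from its probe set with the highest mean, giving 13453 genes. Other probe sets of the same gene can differ from the one used.

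Groups and replicate numbers came from the sample titles. AFO was compared with control by limma 3.58.1 in R 4.3.3 (linear fit, empirical Bayes with a mean-variance trend), unpaired, with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. The 18 gene lists and 11 cell type marker lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Of 436 listed genes 374 were tested, 26 lay below the filter and 36 were not analysed here. Lists were tested by camera with a preset correlation of 0.01, adjusted over the 28 lists with at least 3 tested genes, and the erythroid list with 1 gene was described only. The text names Fto and 7 fat genes, up to 10 called genes with non-overlapping groups in each direction (filled to 5 by smallest unadjusted p where fewer passed), and from each list up to 4 passing members or else the 2 with the smallest p. Predicted genes and clones without a symbol were passed over.

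Both genotypes carry pool numbers 1 to 3, so the pairing of equal numbers was checked. Across genes, which are not independent replicates, the deviations from the genotype means correlated at 0.594, 0.799 and 0.589 for pools 1, 2 and 3. In these deviations each array correlated best with its own number. The rule for pairing asked for every pair to exceed 0.1, which held. Control 1 with AFO 3 (0.441) and control 3 with AFO 1 (0.362) exceeded it as well. With pool 2 apart in both genotypes, pools 1 and 3 deviate the same way whatever the pairing, so the rule cannot test it for them. The labels do not say what a number shares. The unpaired fit stays first, as planned, and the fit with pool number as a block is given where it changes a call. The check and both sets of calls were computed together, and the rule was applied as written.

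Alternatives covered no filter and a filter at the 60th percentile (5.97), quantile normalisation and median centring, the mean of a gene's probe sets, preference for probe sets without _x_at or _s_at endings, empirical Bayes without trend or robust, array weights, pool number as a block, each array left out, all probe sets tested singly, looser thresholds, camera with an estimated correlation, and fry. Omission of both pool 2 arrays, alone and with the block, and the estimated correlation joined to the block, to omitted arrays, to array weights, to no filter or to median centring were chosen after seeing the data. RNA quality was compared by an exact two-sided permutation test.

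The fits were tested on simulated data with the real gene means and spreads for 13453 genes, 50 of them changed at each of 4 sizes. The unpaired fit recovered 44% of changes of 1 log2 unit, 86% of 2, 94% of 3 and 98% of 4, and called 14 unchanged genes. With the block these shares were 48%, 88%, 94% and 96%, with 8 unchanged genes called. Without pool 2 they were 26%, 80%, 90% and 94%, with 0 unchanged genes called. In these simulations the noise is independent between arrays, unlike the shared pool structure of the real data. Many genes change at once in them, which loosens the adjusted cutoff. The shares recovered therefore overstate what the fits would find where few genes change. A list with no simulated change had a camera p of 0.0397 in the unpaired simulation.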

Results

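White fat from male C57BL/6 mice aged 16 weeks was profiled on Affymetrix mouse expression arrays that read the 3' ends of transcripts. The labels place the tissue in the epididymal pad, a visceral depot, and describe mice on a chow diet with free access to food. The design compares 2 genotypes. Control mice carried floxed copies of Fto, which encodes an enzyme that removes methyl groups from RNA, and AFO mice carried the same floxed copies together with a Cre recombinase driven by adiponectin regulatory sequence, which is active in fat cells. Each genotype was represented by 3 arrays, and each array by its own RNA pool, so 6 arrays were analysed. The values are log2 expression levels, with array medians between 5.35 and 5.43, and the number of arrays limits the precision of every comparison.

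Fto was read first, because by the labels the genotypes differ in it. Its probe set above the detection filter (Entrez gene 26383) had a mean level of 5.96 ± 0.33 (SD, n = 3) in control fat and 5.84 ± 0.35 (SD, n = 3) in AFO fat. The difference of -0.12 had a standard error of 0.25 and a 95% interval from -0.71 to 0.47, with a limma adjusted p of 0.999999. The control pools read 6.11, 6.20 and 5.59 and the AFO pools 6.13, 5.45 and 5.95, so the genotypes overlapped. A second Fto probe set lay below the filter, with a difference of -0.0061. The labels do not say which exon is removed, and the position of the Fto probe sets was not compared with it. These values therefore do not check the genotype, which rests on the labels alone.

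The arrays separated first by pool number. The pool 2 arrays of both genotypes stood apart on the first principal component, which held 67.6% of the variance, with coordinates of 37.2 for control and 57.5 for AFO against -19.6 to -28.0 for the other 4 arrays. Tcf21, a transcription factor of visceral mesenchyme, read 7.89 and 8.09 in control pools 1 and 3 and 2.58 in control pool 2, and 7.91, 8.05 and 2.64 in the corresponding AFO pools. Msln, a mesothelial surface protein, read 4.82 in control pool 2 and 4.35 in AFO pool 2, against 8.32 to 8.71 elsewhere. Ms4a1, which encodes the B cell antigen CD20, read 9.26 and 9.84 in the pool 2 arrays and 5.09 to 6.19 in the others. Glycam1, a ligand made by lymph node vessels, read 10.28 and 10.81 in pool 2 and 3.81 to 5.33 in the others. These 4 genes were chosen after their values were seen. By fixed marker lists, the median pool 2 level minus that of pools 1 and 3 was -3.30 for mesothelial genes, 3.51 for B cells, 2.85 for T and NK cells, 2.09 for neutrophils and 4.50 for skeletal muscle, and -0.16 for adipocyte identity genes. Pool 2 is not a group of the study, so no test was made of it.

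**Figure D1:**
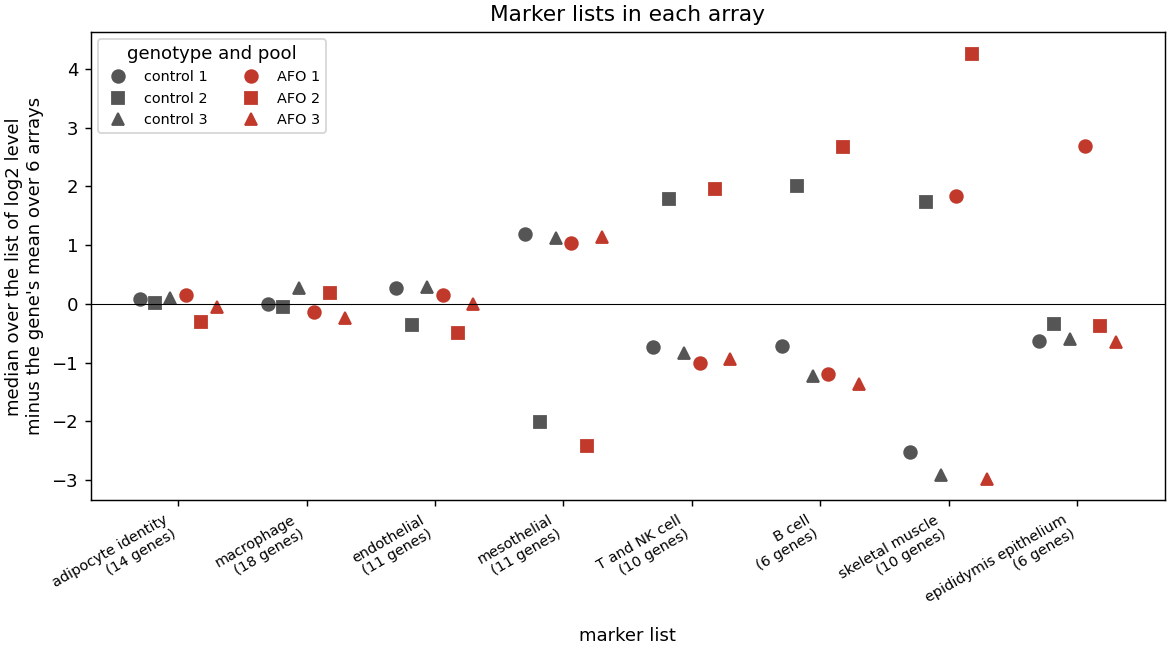
Median of 8 fixed marker lists in each array, as the log2 level minus each gene's mean over the 6 arrays, with control in grey, AFO in red and the pool number given by the symbol. The squares (pool 2) of both genotypes lie apart for mesothelial, T and NK cell and B cell genes, the skeletal muscle list is high in AFO pools 1 and 2 and in control pool 2, and the epididymis list is high in AFO pool 1 alone.

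The comparison of AFO with control fat asks which transcripts differ between mice with and without the Cre that, by the labels, acts on floxed Fto in fat cells. Bex1 (Entrez gene 19716), a brain-expressed X-linked gene, was higher in all 3 AFO pools, by 3.55, 2.74 and 3.59 log2 units within pools 1, 2 and 3. Mlf1 (Entrez gene 17349), myeloid leukemia factor 1, was higher by 2.38, 2.48 and 2.58. With all 13453 genes tested by limma without pairing, 0 genes passed an adjusted p of 0.05, and 139 had an unadjusted p under 0.05 where chance gives 672.65. With pool number as a block, a pairing that the labels do not state, 2 genes passed. These were Bex1 (log2 difference 3.29, SE 0.19, limma adjusted p 0.0171) and Mlf1 (2.48, SE 0.11, limma adjusted p 0.00888). Both were higher in AFO fat in 3 of 3 pools. With the block 581 genes had an unadjusted p under 0.05, also fewer than the 672.65. Mlf1 was chosen after its values were seen, since its groups overlap without the block. Across the 18 alternatives the limma adjusted p of Bex1 ran from 3.3e-11 to 1 and that of Mlf1 from 5.4e-08 to 1. Both lowest values came from the fit without both pool 2 arrays and with the block, chosen after the data were seen. Without AFO pool 2, 27 genes passed in place of 0.

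The genes with non-overlapping groups and the smallest unadjusted p without pairing did not pass. Each had a limma adjusted p of 0.999999, far from the threshold, and their values are given as measured. Fbp2, the muscle isoform of fructose-1,6-bisphosphatase, was at 6.95 ± 0.18 in AFO and 5.57 ± 0.22 in control fat (SD, n = 3), a difference of 1.38 with a standard error of 0.17. Ddit4l, an inhibitor of mTOR signalling, differed by 1.64 (SE 0.28), Slc38a4, an amino acid transporter, by 1.32 (SE 0.24), and Tcea3, a transcription elongation factor, by 0.68 (SE 0.16). On the lower side stood Angpt1, a ligand of the endothelial receptor Tie2, at -0.84 (SE 0.20), Fbxo45, an F-box protein, at -0.46 (SE 0.11), Gdap10 at -0.81 (SE 0.21), Alb, which encodes albumin, at -1.24 (SE 0.32) and Arg1, which encodes arginase 1, at -0.93 (SE 0.26). As the rule for naming them required, in each of these 9 genes the 3 AFO values lay outside the 3 control values. Over all tested genes, 471 had non-overlapping groups, which is 3.50% where chance gives 10%. That 10% and the 672.65 genes above hold for arrays that vary independently, and arrays of equal pool number varied together.

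**Figure D2:**
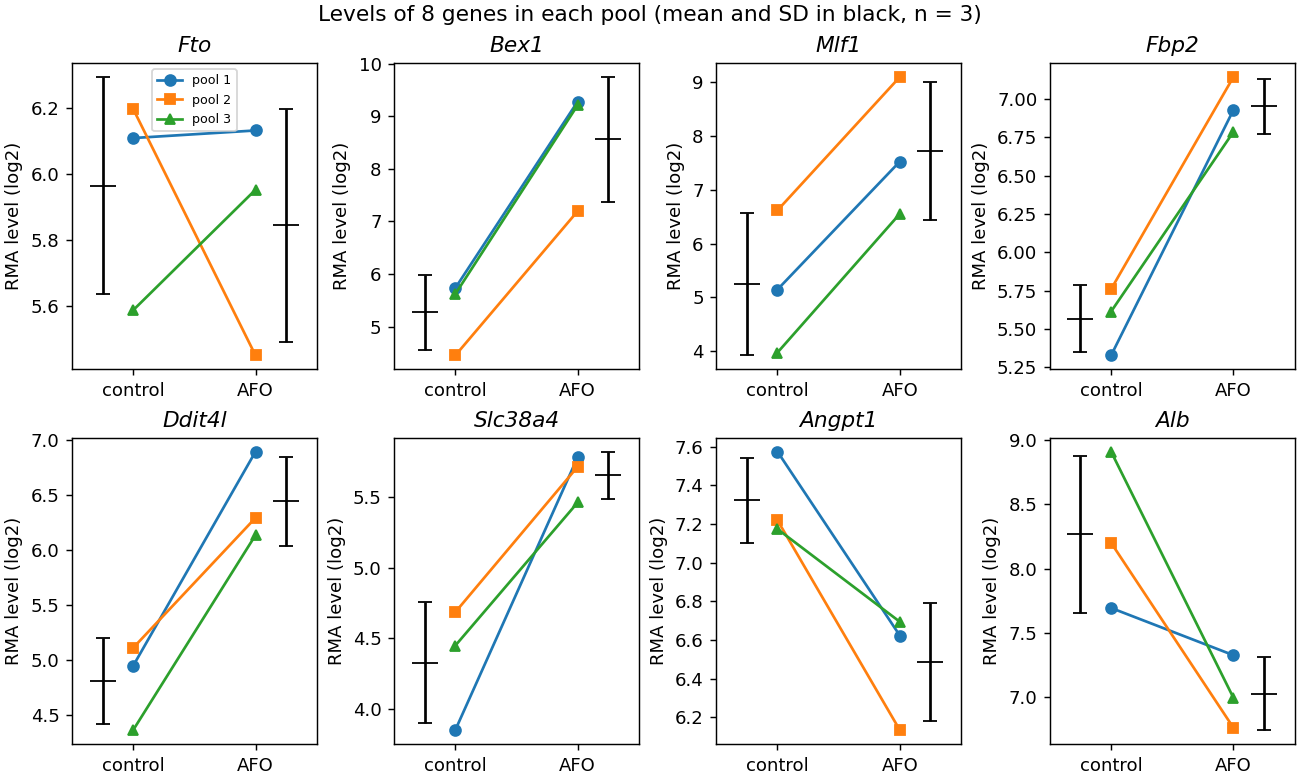
Log2 levels of 8 genes in the 3 control and 3 AFO pools, with lines joining pools of the same number and black bars giving the mean and SD of each genotype (n = 3). Bex1 and Mlf1 rise along all 3 lines, by 2.74 to 3.59 and by 2.38 to 2.58, while the lines of Fto cross.

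Leaving out both pool 2 arrays, an alternative chosen after the data were seen, gave 91 genes, of which 89 rose and 2 fell (Ccr1, a chemokine receptor, and Arg1). The rises were led by Cldn2, a claudin of leaky epithelia (log2 difference 4.27), Ccdc198, a coiled-coil protein (4.09), Calml3 (4.09), Mmp7, an epithelial matrix metalloproteinase (3.96), and Slc7a9, a subunit of the cystine transporter of kidney tubules (3.74). Lcn2, which encodes the secreted protein lipocalin 2, rose by 2.51. Ccr1, Cldn2, Ccdc198, Calml3, Mmp7 and Slc7a9 were chosen after their values were seen. These genes did not stand high in AFO pool 2. Cldn2 read 9.11 and 8.44 in AFO pools 1 and 3, 4.51 in AFO pool 2 and 3.93 to 5.09 in control fat, and Lcn2 read 10.50, 10.60 and 6.78 in AFO pools 1, 3 and 2 against 8.04 to 8.14 in control fat. Of the 91 genes, 33 had a pool 2 difference of the same sign and 5 had one of at least 1 log2 unit, namely Bex1, Mlf1, Fbp2, Ddit4l and Slc38a4. With pool number as a block over the same 4 arrays 270 genes passed, 231 higher and 39 lower, and all 91 were among them. Both fits use the same arrays and the same differences, so the return of the 91 is no separate support. The block leaves still less to measure spread by, and the pairing of pools 1 and 3 could not be tested. Without pool 2 each genotype is represented by 2 arrays.

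Fixed lists of genes were then compared by limma's camera test, which sets a list against all other tested genes. With a preset correlation of 0.01, 8 of 28 lists passed, 2 higher and 6 lower in AFO fat. With the correlation estimated from the data 0 passed (smallest adjusted p = 0.902), and 0 passed with fry, which asks whether a list's genes move one way on balance. The estimated correlations of the 8 lists ran from 0.079 for insulin signalling to 0.97 for skeletal muscle, all above the preset 0.01. In no list did a member pass on its own without pairing, either over all genes or when adjusted over the list alone. Array weights ended the calls of the adipocyte identity (median -0.077, adjusted p = 0.126), lipolysis (-0.10, 0.0914), plasma triglyceride uptake (-0.020, 0.725) and insulin signalling lists (-0.090, 0.0914), and a filter at the 60th percentile those of the macrophage (-0.092, 0.0911) and epididymis lists (0.98, 0.259). With fry, the adjusted p of each of the 8 lists was 0.988, the highest over its 20 alternatives.

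Genes of the fat cell itself were slightly lower in AFO fat as lists. Of 14 tested adipocyte identity genes 13 were lower, with a median of -0.18 (adjusted p = 0.00676, and adjusted p = 0.902 with an estimated correlation). Of 15 genes of lipolysis and the lipid droplet 12 were lower, with a median of -0.20 (adjusted p = 0.00676, and 0.902 as adjusted p with an estimated correlation). None of the 7 genes named in advance passed the limma test. Adipoq, which encodes adiponectin, differed by -0.10 (SE 0.11), Lep, which encodes leptin, by -0.22 (SE 0.62), Pparg, the nuclear receptor of fat cell differentiation, by -0.24 (SE 0.33), and Retn, which encodes resistin, by -0.23 (SE 0.13). The lipases Pnpla2 and Lipe differed by -0.18 (SE 0.22) and -0.34 (SE 0.23), the lipase inhibitor G0s2 by -1.17 (SE 0.42) and the protein kinase A subunit Prkaca by -0.23 (SE 0.14). Within pools 1, 2 and 3 the identity list had medians of -0.0038, -0.36 and -0.18 and the lipolysis list 0.059, -0.36 and -0.25. Markers of other cells also differed within pools, with medians in pools 1, 2 and 3 of 4.34, 2.53 and -0.18 for skeletal muscle, -0.17, 0.95 and -0.16 for neutrophils, -0.44, 0.61 and -0.14 for B cells and -0.19, 0.20 and -0.36 for macrophages. In pool 2, where both fat cell lists were lowest, all 4 were higher in AFO fat. Other marker lists were lower there, with medians of -0.40 for mesothelial, -0.20 for endothelial, -0.13 for epididymis and -0.062 for smooth muscle genes. No test parted a lower level per fat cell from a lower share of fat cells. Both calls ended without AFO pool 2 (medians -0.019 and -0.012, adjusted p = 0.444 and 0.333) and without the 2 pool 2 arrays (-0.074 and -0.072, 0.498 and 0.204). That of the identity list also ended without control pool 2, where its median was still -0.17 (0.0836). Over the alternatives their lowest adjusted p, both with the preset correlation, were 6.9e-05 and 1.9e-05.

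Genes of fat uptake from plasma and of insulin signalling were also lower as lists. Of 16 genes of plasma triglyceride uptake 15 were lower, with a median of -0.12 (adjusted p = 0.0109, and adjusted p = 0.953 with an estimated correlation). Lpl, the lipoprotein lipase of capillaries, differed by -0.15 (SE 0.11), its inhibitor Angptl4 by -0.12 (SE 0.40) and the fatty acid transporter Slc27a1 by -0.39 (SE 0.19), none passing. Of 18 insulin signalling genes 16 were lower, with a median of -0.12 (adjusted p = 0.0206, and adjusted p = 0.902 with an estimated correlation), among them the receptor substrate Irs2 at -0.38 (SE 0.23) and the phosphodiesterase Pde3b at -0.21 (SE 0.14). Within pools 1, 2 and 3 the uptake list had medians of 0.078, -0.40 and -0.25, and in pool 1 13 of its 16 genes were higher in AFO fat. The insulin list had medians of -0.0026, -0.15 and -0.20, with 8 of its 18 genes higher in pool 1. The uptake list turned to 0.031 without AFO pool 2 (adjusted p = 0.941) and lost its call without control pool 3 (median -0.034, 0.292) or the 2 pool 2 arrays (-0.036, 0.487). The insulin list lost its call without control pool 3 (-0.071, 0.152), AFO pool 2 (-0.094, 0.238) or AFO pool 3 (-0.091, 0.0963). It also lost it without control pool 1 (0.0910) or the 2 pool 2 arrays (0.105), where its median stayed at -0.12. Over the alternatives their lowest adjusted p, both with the preset correlation, were 0.000296 and 0.00637.

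Synthesis of fat and sterols did not pass. De novo lipogenesis had 12 of 17 genes lower and a median of -0.087 (adjusted p = 0.480), with the desaturase Scd2 at 0.59 (SE 0.21) and the carboxylase Acaca at -0.30 (SE 0.19). Triglyceride synthesis had 9 of 13 lower and a median of -0.092 (adjusted p = 0.226), with the acyltransferase Dgat1 at -0.34 (SE 0.16) and the phosphatase Lpin2 at 0.26 (SE 0.16). With pool number as a block this list passed (adjusted p = 0.0453, and adjusted p = 0.779 with an estimated correlation), and 1 member, the acyltransferase Gpat3 at -0.48 (SE 0.10 with the block), passed when adjusted over the list alone. Cholesterol synthesis had 11 of 18 lower and a median of -0.079 (adjusted p = 0.494), with Sc5d at -0.32 (SE 0.22) and Insig1 at -0.23 (SE 0.22). Without AFO pool 1 lipogenesis had a median of -0.24 (adjusted p = 0.0225, and adjusted p = 0.711 with an estimated correlation), and without control pool 1 triglyceride synthesis had one of -0.18 (adjusted p = 0.0212, and adjusted p = 0.869 with an estimated correlation). Over the 20 alternatives the adjusted p of these 2 lists reached 0.988.

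Lists of fat burning did not pass without pairing. Fatty acid oxidation had 11 genes higher and 11 lower, with a median of 0.0044, a mean of -0.0014 and a test direction of lower (adjusted p = 0.899), with the pyruvate dehydrogenase kinase Pdk4 at 0.44 (SE 0.22) and the thiolase Acaa1a at -0.25 (SE 0.14). Oxidative phosphorylation had 15 of 29 genes higher and a median of 0.0026 (adjusted p = 0.494), with the respiratory chain subunits Ndufs3 at 0.11 (SE 0.12) and Uqcrfs1 at 0.12 (SE 0.14). The thermogenic list had 10 of 13 genes higher and a median of 0.085 (adjusted p = 0.746), with the regulator Prdm16 at -0.33 (SE 0.14). With the block it passed (adjusted p = 0.0453, and adjusted p = 0.779 with an estimated correlation), and 2 members passed over the list alone, Cox7a1 at 1.80 (SE 0.43 with the block) and Cox8b at 1.05 (SE 0.15 with the block). Both encode cytochrome oxidase subunits found in muscle as well as brown fat, and the skeletal muscle markers were also higher in AFO pools 1 and 2. Leaving out AFO pool 3 or control pool 2 brought oxidative phosphorylation to adjusted p of 0.000147 and 0.00911, with medians of 0.11 and 0.073, and leaving out control pool 2 brought the thermogenic list to 0.0212, with a median of 0.25. With an estimated correlation the adjusted p was 0.809 without AFO pool 3 and 0.629 for both lists without control pool 2. Over the 20 alternatives the adjusted p of both lists reached 0.988.

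Macrophage and endothelial markers were lower as lists. Of 18 macrophage genes 17 were lower, with a median of -0.094 (adjusted p = 0.0301, and adjusted p = 0.953 with an estimated correlation), among them Cd14, a receptor for bacterial lipopolysaccharide, at -0.25 (SE 0.15) and the integrin Itgam at -0.50 (SE 0.39). The macrophage medians within pools 1, 2 and 3 were -0.19, 0.20 and -0.36, and in pool 2 16 of the 18 genes were higher in AFO fat. All 11 tested endothelial genes were lower, with a median of -0.17 (adjusted p = 0.00943, and adjusted p = 0.953 with an estimated correlation), among them the VEGF receptors Kdr at -0.37 (SE 0.21) and Flt1 at -0.25 (SE 0.17). The endothelial medians within pools 1, 2 and 3 were -0.091, -0.20 and -0.30. Cytokine and inflammation genes had 11 of 15 lower and a median of -0.20 (adjusted p = 0.0583), with the acute phase gene Saa3 at -1.29 (SE 0.49) and Tlr4 at -0.31 (SE 0.23). Without the 2 pool 2 arrays the macrophage list had a median of -0.31 (adjusted p = 5.8e-07), the endothelial list -0.21 (0.0157) and the cytokine list -0.28 (0.0324), and with an estimated correlation the adjusted p of these 3 was 0.580. The macrophage call ended without control pool 3 (-0.0022, 0.811) or AFO pool 3 (-0.024, 0.395), and without AFO pool 1 at a median of -0.088 (0.660). The endothelial call ended without control pool 1 (-0.12, 0.175), control pool 3 (-0.058, 0.263) or AFO pool 2 (-0.015, 0.814). The cytokine list passed without control pool 1 (-0.23, 0.0131) or AFO pool 2 (-0.28, 0.0162), with no filter on dim probe sets (-0.16, 0.0290) and with median centring (-0.19, 0.0408). With an estimated correlation the adjusted p of these 4 was 0.869, 0.946, 0.848 and 0.928. Over the alternatives the lowest adjusted p of the macrophage and endothelial lists, with the preset correlation, were 1.6e-07 and 3.6e-05. The cytokine list ran from 0.0131 to 0.988.

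Markers of skeletal muscle and of the epididymal duct were higher in AFO fat as lists, each through particular pools. All 10 tested skeletal muscle genes were higher, with a median of 2.27 (adjusted p = 2.8e-05, and adjusted p = 0.902 with an estimated correlation). The median difference was 4.34 in pool 1, 2.53 in pool 2 and -0.18 in pool 3. Myh4, a fast myosin heavy chain, read 9.84, 12.31 and 3.44 in AFO pools 1, 2 and 3 and 3.48, 10.28 and 3.13 in the control pools. Mb, which encodes myoglobin, differed by 1.83 (SE 1.04) and Ckm, the muscle creatine kinase, by 2.43 (SE 1.78). With the block all 10 passed over the list alone, and 0 passed over all genes. Of 6 epididymis genes 5 were higher, with a median of 1.05 (adjusted p = 0.0109, and adjusted p = 0.902 with an estimated correlation), and the pool medians were 3.28, -0.13 and 0.0039. Lcn9, an epididymal lipocalin, differed by 0.98 (SE 0.73) and Rnase10 by 1.12 (SE 0.86). The muscle call ended without AFO pool 2 (median 0.75, 0.444) or control pool 3 (1.58, 0.0652), and the epididymis call without AFO pool 1 (-0.031, 0.962) or control pool 3 (0.98, 0.274). Over the alternatives their lowest adjusted p were 3.3e-20 and 1.2e-06. Both came with the preset correlation, while the correlation estimated from the data was 0.97 for skeletal muscle and 0.60 for epididymis genes.

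Among the other cell type markers, no list passed without pairing. T and NK cell genes had a median of -0.093 with a test direction of higher (adjusted p = 0.948), with Cd8a at 0.23 (SE 0.22) and Cd3e at -0.21 (SE 0.43). B cell genes had a median of 0.0072 (0.936), with Ms4a1 at -0.16 (SE 1.56) and Cd79b at 0.13 (SE 1.43), and neutrophil genes 0.027 (0.936), with Ngp at 0.86 (SE 0.77) and Elane at -0.14 (SE 0.16). Mesothelial genes had a median of -0.18 (0.746), with Krt19 at -0.76 (SE 0.84) and Lrrn4 at -0.56 (SE 1.38), and passed with the block (adjusted p = 0.00637, and adjusted p = 0.779 with an estimated correlation). Fibroblast and preadipocyte genes had a median of 0.058 (0.770), with Dpt at -0.19 (SE 0.17), and smooth muscle genes -0.13 (0.480), with Des at 0.63 (SE 0.56) and Tagln at -0.31 (SE 0.32). A smooth muscle gene, Cnn1 at -0.52 (SE 0.12 with the block), passed over the list alone with the block. Alas2, the single tested erythroid gene, was at -0.75 (SE 0.23 with the block) and did not pass over all genes (adjusted p = 0.990 with the block). Leaving out either pool 2 array moved these lists. Without control pool 2 the medians were 0.76 for T and NK cells, 0.97 for B cells, -1.26 for mesothelial and -0.52 for smooth muscle genes (adjusted p of 0.00893, 0.0393, 0.0159 and 0.00844). With an estimated correlation the adjusted p of these 4 was 0.629. Without AFO pool 2 the medians were -1.05, -1.29, 0.97 and -0.63 for T and NK, B, mesothelial and neutrophil genes (adjusted p of 0.00249, 0.00718, 0.00121 and 0.00914, and adjusted p = 0.946 for each with an estimated correlation). Mesothelial and smooth muscle genes also passed without AFO pool 3 (-0.78 and -0.30, adjusted p = 0.0491 for each, and adjusted p = 0.809 with an estimated correlation), and smooth muscle genes with array weights (-0.32, adjusted p = 0.0124, and adjusted p = 0.923 with an estimated correlation). Without both pool 2 arrays B cell genes (-0.27, 0.0440) and smooth muscle genes (-0.18, 0.0324) were lower, and with an estimated correlation the adjusted p of both was 0.580. Over the 20 alternatives the adjusted p of these lists reached 0.988 or above.

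The lists closest to Fto itself and to the handling of the tissue did not pass. RNA m6A machinery, the enzymes and readers of the mark that Fto removes, had 11 of 17 genes lower and a median of -0.022 (adjusted p = 0.853), with the reader Ythdc1 at -0.18 (SE 0.15) and the writer component Zc3h13 at 0.15 (SE 0.14). Of the genes beside Fto on its chromosome all 4 tested were higher, with a median of 0.063 (0.480), among them Rbl2 at 0.21 (SE 0.15) and Aktip at 0.12 (SE 0.36). Adipokines had a median of -0.11 and a mean of 0.035 (0.675), with Lcn2 at 1.22 (SE 0.99). Extracellular matrix genes had a median of -0.035 with a test direction of higher (0.853), with the collagen genes Col1a1 at 0.56 (SE 0.24) and Col1a2 at 0.22 (SE 0.15). Immediate early genes had a median of -0.0037 with a test direction of higher (0.583), with Ier3 at 0.26 (SE 0.19) and Atf3 at 0.19 (SE 0.15). Circadian clock genes had a median of 0.037 (0.746), with Per2 at 0.32 (SE 0.42) and Cry2 at 0.12 (SE 0.27), and the unfolded protein response -0.079 (0.369), with Sdf2l1 at -0.40 (SE 0.30) and Asns at -0.34 (SE 0.30). Leaving out single arrays let 3 of these lists pass. Extracellular matrix did so without control pool 2 (-0.34, adjusted p = 0.00911), immediate early genes without AFO pool 3 (0.15, 0.00463), and the unfolded protein response without AFO pool 1 (-0.17, 0.0414) or control pool 2 (-0.21, 0.0212). With an estimated correlation the adjusted p was 0.629 for both lists without control pool 2, 0.809 for immediate early genes and 0.816 for the unfolded protein response without AFO pool 1. Their adjusted p reached 0.988 over the 20 alternatives.

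**Figure D3:**
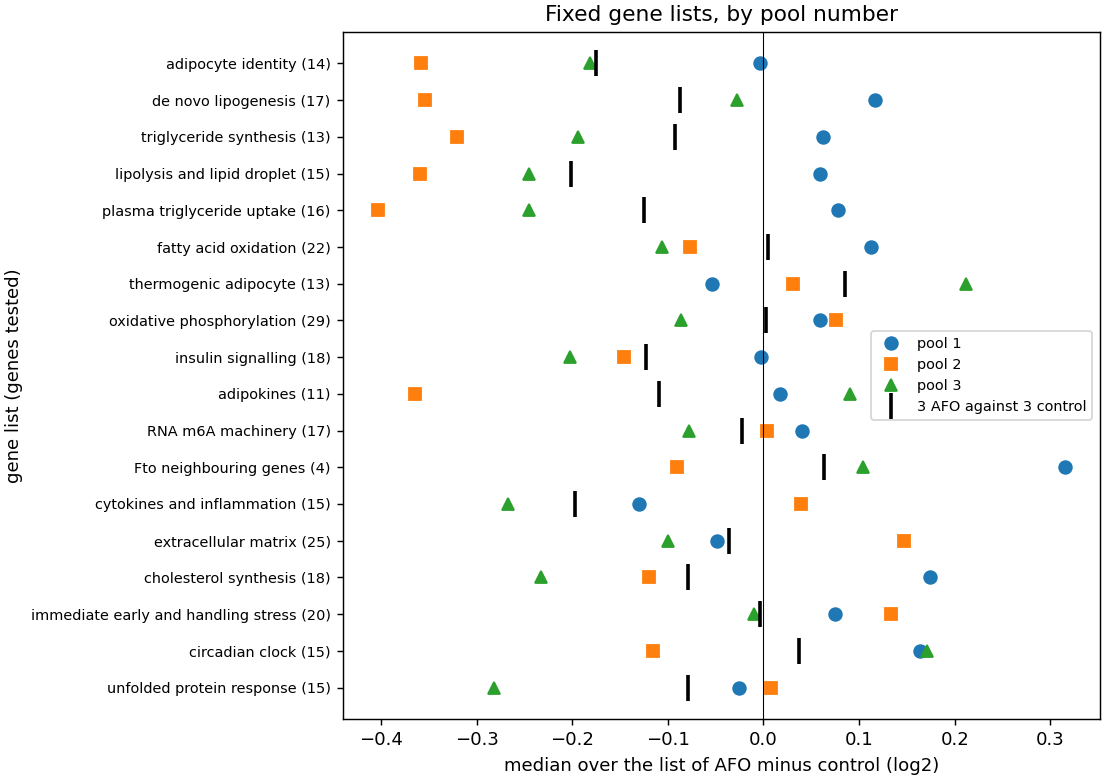
Median log2 difference, AFO minus control, of the 18 fixed gene lists within each pool number (symbols) and over all 6 arrays (black bars), with the number of tested genes in brackets. For adipocyte identity the symbols lie at -0.0038, -0.36 and -0.18 for pools 1, 2 and 3, and for plasma triglyceride uptake at 0.078, -0.40 and -0.25.

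RNA quality was read from the 3' minus 5' difference of the Gapdh and Actb control probe sets, averaged over both. It was 0.473 ± 0.097 (SD, n = 3) log2 units in control and 0.562 ± 0.260 (SD, n = 3) in AFO fat. The difference of 0.089 had an exact two-sided permutation p of 0.9, where 3 arrays against 3 cannot give less than 0.1. AFO pool 3 stood highest at 0.858, against 0.367 to 0.567 in the other 5 arrays.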

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

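The tests of diluted gonadal fat, of epididymal duct and of skeletal muscle were chosen after the results were seen, as were the 5-gene set and the omission of pool 2. The lists of subcutaneous, visceral and motile cilia genes were written after the principal components were seen and before their members were read.

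Outside the tested genes, 31584 probe sets remained, and in 2 of them every AFO array stood more than 1 log2 unit above every control array, as it did in 3 of the tested genes. One, for which the annotation used here gives no single gene, read 5.76, 5.98 and 5.86 in AFO and 3.53, 3.84 and 3.51 in control fat, a gap of 1.92. The other, a second Ddit4l probe set, read 7.23, 6.05 and 6.03 against 4.61, 4.83 and 4.29, a gap of 1.20.

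The pool 2 arrays of both genotypes had low Tcf21 and mesothelial transcripts and high lymphoid and muscle transcripts. Lymph node and muscle added to gonadal fat would lower mesothelial and adipocyte genes alike, but the mesothelial minus the adipocyte identity shift was -3.15 log2 units in the genotype where it was smaller, which argues against dilution. Fat from a subcutaneous depot stays open: the subcutaneous minus visceral list difference in pool 2 was at least 1.58 in both genotypes. That value came mostly from visceral genes (-1.38 in control, -1.43 in AFO), with subcutaneous genes at 0.39 and 0.15. It thus allows another depot but rests mostly on what was missing. Among the subcutaneous genes, Shox2 read 7.75 and 7.03 in control and AFO pool 2 and 4.35 to 4.99 elsewhere. Hoxc10 read 7.72 in control pool 2 against 5.33 and 4.29 in control pools 1 and 3. In AFO pool 2 it read 6.23, between the 6.84 and 5.04 of AFO pools 1 and 3. Hoxc9 stayed at 6.29 to 6.61 in all 6 arrays. Sfrp2 went the other way, at 6.89 and 7.33 against 7.70 to 8.31. The labels give the same epididymal tissue for all 6 arrays, and no biological explanation was tested.

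Epithelial and cilia genes (Cldn2, Mmp7, Prom1, Tmem212) were high in AFO pools 1 and 3 and at about control level in AFO pool 2. Epididymal duct carried over with the fat may account for part of AFO pool 1, where the median epididymis marker stood 2.78 log2 units above the highest control array, with Lcn8 at 8.72 against 4.44 to 4.92 in control fat. In AFO pool 3 that median was -0.26, which argues against duct that expresses these markers there. It cannot exclude an epithelium without these markers that AFO pools 1 and 3 share, in which Cldn2 read 9.11 and 8.44. Motile cilia genes in AFO pool 3 stood 0.45 above the highest control array, short of the 0.5 set in advance for ciliated epithelium, yet 18 of the 20 listed genes lay above every control array there and 16 in AFO pool 1, a count made after the result was seen. Ciliated epithelium in that pool stays open, as does an effect of genotype on such cells, which is untested.

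Bex1, Mlf1, Fbp2, Ddit4l and Slc38a4 were higher in every AFO pool than in the control pool of the same number, with medians of 1.95, 1.38 and 1.78 log2 units in pools 1, 2 and 3. Skeletal muscle as the only carried-over tissue would need muscle markers to be higher in every pool. Over all 11 markers, the 1 below the filter included, their median difference was 4.28 in pool 1, 2.54 in pool 2 and -0.14 in pool 3. Duct or ciliated epithelium as the only source would need one of their lists to be higher in every pool, but the larger of the 2 was -0.071 in pool 2. Motile cilia genes were higher in pools 1 and 3 (0.71 and 0.86). The 5 genes are those of the 91 called without pool 2 that also rose by at least 1 log2 unit there. Their rise in every pool follows from that choice, so neither comparison can set carried-over tissue aside. Different tissues in different pools were not tested as a joint source. A response to Fto loss, an effect of the Cre transgene or its strain background, and other tissue may each account for these genes, and the design does not separate them, since by the labels AFO mice differ from control mice in both Cre and Fto.

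Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. Without pairing the real split gave 0 genes and the highest other 0, and since no split can give fewer this comparison says nothing about the grouping. For lists the real split gave 8 and the highest other 14, and 6 of 10 gave as many. Splits with both pool 2 arrays on one side had up to 2419 genes at an unadjusted p under 0.05 against 139 for genotype, which points to the structure of the pools. With the block the real assignment gave 2 genes and the highest of the other 3 ways to part the pairs gave 0, and 4 ways are again too few for a share under 0.05. At an unadjusted p under 0.05 the real assignment had 581 genes with the block, and exchanging the genotypes within pool 2 had 814.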

How the results depend on the processing

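The settings without both pool 2 arrays and the estimated correlation joined to another setting were chosen after seeing the data. The count of 0 genes stayed at 0 under the filters, scalings, probe set rules, variance models and array weights, with all probe sets tested singly (250 of 27022 at an unadjusted p under 0.05) and at an adjusted p under 0.1. It was 2 with pool number as a block, 139 at an unadjusted p under 0.05, 91 without both pool 2 arrays and 270 without them and with the block, and 0 to 27 with single arrays left out (27 without AFO pool 2). The count of 8 lists was 5 with array weights, 0 with an estimated correlation, 0 with fry, 0 with an estimated correlation and the block, 0 with an estimated correlation in each of 10 further settings (every single array left out, both pool 2 arrays left out, array weights, no filter and median centring), and 2 to 15 with single arrays left out. It was 9 with no filter and with median centring, the cytokine list being added in each. With the block over all 6 arrays it was 11, and the block there changed no other call than those given with the results. Without both pool 2 arrays it was 7, and 8 when the block was added. Of the 8 lists called, 4 remained with array weights, 6 with the filter at the 60th percentile, 2 without control pool 3, 2 without AFO pool 2 and 4 without both pool 2 arrays. With single arrays left out, list medians that turned ranged from -1.05 to 0.76 for T and NK cells, -0.031 to 1.65 for epididymis, -0.24 to 0.031 for plasma triglyceride uptake, -1.29 to 0.97 for B cells, -0.63 to 0.59 for neutrophils, -1.26 to 0.97 for mesothelial and -0.035 to 0.15 for immediate early genes. B cell genes turned to -0.27 without both pool 2 arrays, with or without the block. Fto passed in no setting. It had no value at the 60th percentile, and its sign changed in 3 settings (0.078 without AFO pool 2, 0.19 without both pool 2 arrays, with or without the block). Values on the same side of the threshold also changed sign in 67 cases for lists and 35 for named genes, and 28 cases of named genes passed only in an alternative. RNA quality differed by 0.11 with Gapdh alone and 0.073 with Actb alone. Robust empirical Bayes gave no list test, and the array weights stopped before their convergence tolerance. Signal over background limits what a difference can show for genes near the filter level of 4.88. Apart from the smaller number of arrays where some were left out, the cause was not tested.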

Other observations

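The test of the genes beside Adipoq was chosen before their values were seen, and the genes of the next paragraph after.

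The fixed thermogenic list had a pool 2 median of 0.38 log2 units against pools 1 and 3. Ucp1, the uncoupling protein of brown fat, read 9.22 in AFO pool 2 and 5.79 in control pool 2, against 4.19 to 4.54 in the other 4 arrays. Cidea, a lipid droplet protein of brown fat, read 10.63 and 10.36 in the pool 2 arrays, 7.31 in AFO pool 1 and 4.46 to 5.45 in the other 3. Prdm16, a regulator of brown fat, read 5.78 in AFO pool 2, the lowest of the 6 arrays, and 6.38 in control pool 2, the highest. Tbx15, a transcription factor of subcutaneous fat, read 6.97 and 7.65 in pool 2 and 4.77 to 5.55 elsewhere. Extracellular matrix and smooth muscle lists were lower in pool 2, with medians of -0.83 and -0.88 against pools 1 and 3. Esr1, the estrogen receptor, read 9.69 and 9.65 in AFO pools 1 and 3, 8.05 in AFO pool 2 and 8.67 to 8.73 in control fat.

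A Cre transgene built on a large fragment around Adipoq could carry extra copies of neighbouring genes, a hypothesis about the construct, whose size the labels do not give. The 7 tested neighbours among 10 considered had a median difference of 0.097 log2 units in AFO fat, at the 96.66th percentile of 10000 random lists matched on level, just past the 95th set in advance. Each neighbour's own difference was smaller than its standard error (Rfc4 0.12, SE 0.19, and Hrg 0.097, SE 0.12), so the shift is small and the hypothesis stays weak.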
